A study of Mus musculus with 14 samples.

How the data were processed

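RNA of GFP-positive cells from the adult mouse dentate gyrus was measured in 14 libraries, 5 labelled GFP+ROS+, 5 labelled GFP+ROS++ and 4 labelled GFP+ROS+++, from the strain B6.Cg-Tg(Nes-EGFP)1Yamm. Per the labels' protocols, the tissue was digested enzymatically, sieved, and sorted on GFP and dihydroethidium fluorescence. Reverse transcription used a poly-dT primer and template switching, and the cDNA was amplified over 12 cycles, sheared by ultrasound and made into fragment libraries. The steps described keep no record of the strand and add no molecular identifiers. The labels give no treatment, batch, animal, sex or pairing. The library numbers in the sample titles repeat the order of the classes. The numbers, and sets cut from them, were used only in alternatives. Replicate numbers here follow the order of the samples in the series. Classes are written ROS+, ROS++ and ROS+++ in the text.

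The authors deposited 1 table of log2 values for 15119 genes by Ensembl identifier in 14 columns, although its name speaks of counts. Per the submitters' processing notes, STAR and edgeR were used with genome build mm10. Which step each served, the counting tool, the annotation and all versions are not given in the sources used here. The deposited log2 values are binary logarithms of counts per library total with a small prior, as read from the values themselves. All libraries share 1 lowest value, -4.36, and their linear values sum to 1000736. After subtraction of the lowest value, every value is a whole multiple of 1 step per library within 0.001 reads. The lowest value equals a prior of 1 read in a library of mean size. No scaling factor between libraries beyond the total over the listed genes was found. Genes with low values appear to have been removed before deposit, since every listed gene has over 1 CPM in at least 3 libraries and at least 82 reads in all.

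From these values the reads were recovered and scaled to each library's total over the listed genes to give CPM. All 14 columns were used. Of the 15119 genes, 15060 have a symbol and 59 only an identifier. Symbols were matched to GENCODE mouse annotation M21, which also gave coordinates and may differ from the annotation the authors used. Recovered totals per class are given with the results. A count of 0 allows up to 3 reads at 95% confidence. The 26 pairs of replicates within a class had a chi-square per degree of freedom of 33.7 to 161 and Pearson correlations of 0.873 to 0.967 across genes, so that no pair differed by counting error alone and none is a repeated run of 1 library.

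The plan made before the data were examined fixed the sample groups, the comparisons, the tests, the gene lists, the rule for named genes and the alternatives. It foresaw counts and, for a file of normalized values, limma-trend on log2(value + 1). Because the deposited unit is log2, limma-trend was used, and edgeR was not run. Values were log2(CPM + 1), with CPM from library totals and a pseudocount of 1 CPM. Genes needed at least 1 CPM in at least 4 libraries, which kept 15102 and removed 17. All 14 libraries entered 1 linear model with a mean for each class and 11 residual degrees of freedom, moderated with a mean-variance trend and robust settings in limma 3.58.1 with statmod 1.5.0 in R 4.3.3. The comparisons were ROS++ minus ROS+, ROS+++ minus ROS+ and ROS+++ minus ROS++, and an F-test asked for any difference among the 3 classes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A gene's libraries were said not to overlap when every library of 1 class lay above every library of the other. The standard errors are the moderated ones of the model. Principal components were computed on centred, unscaled values of the tested genes.

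The 27 gene lists, set from textbook knowledge, were: radial glia-like stem cell, mature astrocyte, neuronal commitment, mature neuron, cell cycle, cyclin-dependent kinase inhibitors and quiescence, oligodendrocyte precursor, myelinating oligodendrocyte, endothelial, mural, leptomeningeal fibroblast, microglia and macrophage, ependymal and choroid plexus, erythroid, antioxidant defence and NRF2 targets, NADPH oxidases and other oxidant producers, glycolysis, fatty acid oxidation, lipogenesis and cholesterol synthesis, Notch signalling, dissociation stress and immediate early, p53 targets and apoptosis, unfolded protein response, interferon response, nuclear-encoded respiratory chain, mitochondrially encoded protein genes, and cytosolic ribosomal proteins. Lists with at least 5 members tested were compared with all other genes by camera in limma with a preset correlation between genes of 0.01, on the same log2(CPM + 1) matrix, with adjustment over the lists of each comparison. The erythroid list had 3 members and is reported by its genes only. Members were also adjusted over their list alone. Fry, which tests a list by itself, and camera with a correlation estimated from the residuals were run as alternatives.

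Named genes followed a rule with 3 parts. For each comparison these were the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05, mean log2 of at least 2, classes that do not overlap and a name that is not a predicted one. Up to 3 members of each list with the smallest p were added, and always preset markers of the precursor stages, among them Nes, Sox2, Gfap, Hopx, Eomes, Dcx and Mki67. Some genes that the rule gave are not reported here. Some list members appear in more than 1 list, as said where it matters.

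The analysis was tested on simulated data first. Reads were drawn for the real genes from the real means, dispersions and library sizes, with seeded genes changed by 2-fold or 4-fold. For ROS++ versus ROS+ (15009 genes in the step) 29.3% of 2-fold and 73% of 4-fold changes were recovered, with 4.67% of calls false. For ROS+++ versus ROS+ (15022 genes) these were 38% and 77.6%, with 3.39% false, and for ROS+++ versus ROS++ (15019 genes) 33% and 68%, with 2.88% false. Of 20 lists of unchanged genes, 0 were called in each comparison. The genes were drawn independently, so this does not cover lists whose members vary together, as those of the mural and macrophage lists did (mean residual correlations 0.811 and 0.438). Known scaling factors were recovered within 0.0047 log2 units.

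Alternatives planned from the start were relative log expression and upper-quartile scaling factors, both written out on the recovered reads, no filter, a strict filter (at least 10 reads in at least 10 libraries, 13963 genes), limma-voom with sample quality weights, a model with only the 2 classes compared, the library number as covariate, pseudocounts of 0.5 and 5, leaving out each library in turn, fry, and camera with an estimated correlation. DESeq2 and svaseq were in the plan for a file of counts and were not run, although reads could be recovered. Chosen after the data were seen were TMM factors written out on the recovered reads, the log2 values exactly as deposited, the first principal component of the residuals as covariate, a block for 5 sets of consecutive library numbers, joint removal of ROS+++ replicate 1 and ROS++ replicate 5, and camera on log2 CPM with a prior count of 2. Other splits of the libraries, 100 drawn with a fixed seed, were fitted in the same way. Data handling and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.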

Results

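RNA was sequenced from adult mouse hippocampal precursor cells sorted by their content of reactive oxygen species (ROS). The cells came from the dentate gyrus of mice that carry enhanced green fluorescent protein under the Nestin gene's regulatory elements, so that GFP marks cells with the Nestin intermediate filament programme of neural stem and progenitor cells. A cell sorter separated them on GFP and on dihydroethidium, a dye that turns fluorescent when superoxide and other oxidants act on it. All 3 classes were GFP-positive and are named by their dye signal: ROS+ (5 libraries), ROS++ (5 libraries) and ROS+++ (4 libraries). The comparisons ask how gene expression differs between precursor classes defined by ROS content, as the series' title states.

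The 15119 listed genes held 20832009 to 25313902 reads per ROS+ library, 18325361 to 23454022 per ROS++ library and 12704227 to 20998589 per ROS+++ library. Between 13341 and 14764 genes had at least 10 reads in a library. The 10 most abundant genes took 5.81 to 6.96% of reads in ROS+, 5.62 to 7.23% in ROS++ and 11.2 to 12.1% in ROS+++. A count of 0 allows up to 3 reads, or 0.119 to 0.236 CPM (reads scaled to library totals) depending on the library, and this floor covers counting error only because the reads were amplified without molecular identifiers. Levels below are mean CPM ± SD over the 5, 5 and 4 libraries. Changes are on the log2(CPM + 1) scale with their standard error (SE), which understates the change of genes near 0 in one class. The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples, which may be technical.

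Most of the variation between libraries followed the sort. The first principal component of the log2(CPM + 1) values held 58.9% of the variance and the second 13.4%. The limma F-test over the classes called 9294 of 15102 tested genes different at an adjusted p under 0.05. Of these, 4274 (46.0%) were highest in ROS+ and lowest in ROS+++, 2241 (24.1%) were highest in ROS+++ and lowest in ROS+, and 1503 (16.2%) were highest in ROS++ and lowest in ROS+++. Another 688 genes (7.403%) were highest in ROS++ and lowest in ROS+. The remaining patterns held 396 genes (ROS+ highest, ROS++ lowest) and 192 genes (ROS+++ highest, ROS++ lowest). These patterns rest on library totals and were not counted with other scalings. Their balance depends on the scaling, since 32.5% of calls between ROS+++ and ROS+ were higher with library totals and 50.7% with relative log expression factors.

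**Figure D1:**
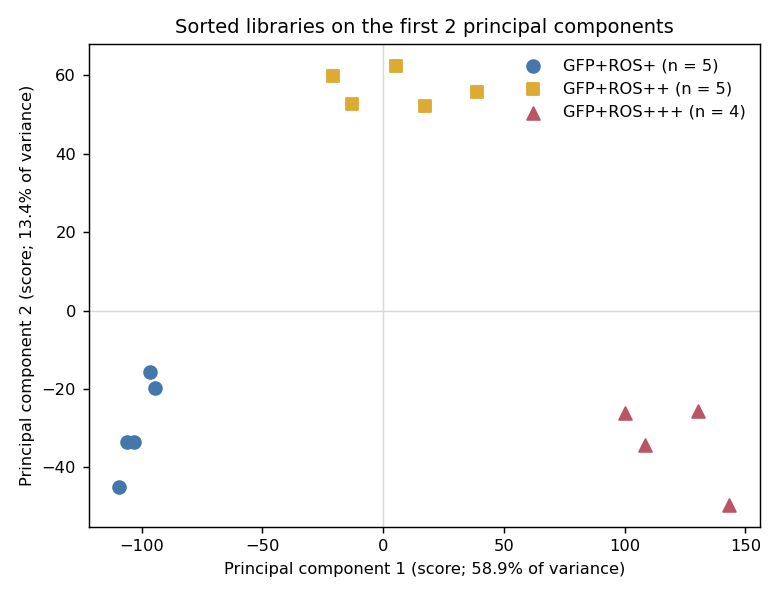
Scores of the 14 libraries on the first principal component (x axis, 58.9% of variance) and the second (y axis, 13.4%) of log2(CPM + 1) values, 1 point per library coloured by ROS class. The libraries fall into their sorted classes along the first component.

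Markers of successive stages of hippocampal neurogenesis separated the classes. Nes itself (chromosome 3, 87971078 to 87980451, ENSMUSG00000004891) averaged 16.6 ± 4.63 CPM in ROS+, 95.5 ± 18.8 CPM in ROS++ and 227 ± 77.7 CPM in ROS+++, and rose at both steps by 2.48 ± 0.23 and 1.19 ± 0.24 (adjusted p = 2.27e-07 and 0.000716). Gfap, the glial filament of radial glia-like stem cells and astrocytes, averaged 7.49 ± 7.401, 179 ± 53.6 and 128 ± 65.8 CPM, and Hopx, a marker of quiescent radial glia-like cells, 1.55 ± 1.51, 52.1 ± 56.8 and 34.2 ± 20.4 CPM. Both rose from ROS+ to ROS++, by 4.82 ± 0.52 and 3.75 ± 0.70 (adjusted p = 4.82e-06 and 0.000558), and neither difference between ROS+++ and ROS++ passed the test. The proliferation marker Mki67 was highest in ROS++, with 29.5 ± 18.5, 95.5 ± 44.8 and 4.91 ± 5.45 CPM. Eomes (chromosome 9, 118478212 to 118486132, ENSMUSG00000032446), which marks neuronal intermediate progenitors, reached 46.6 ± 12.7 CPM in ROS+ and 68.8 ± 14.2 CPM in ROS++ but only 0.179 ± 0.0437 CPM in ROS+++. Dcx, a microtubule protein of neuroblasts, was highest in ROS+ at 444 ± 62.4 CPM, against 81.5 ± 25.3 CPM in ROS++ and 3.17 ± 3.803 CPM in ROS+++. Sox2, a stem and progenitor transcription factor, averaged 27.6 ± 4.78, 55.1 ± 18.7 and 13.4 ± 8.67 CPM. Nes was thus highest in the class where Sox2 was lowest, and the mural list also rose at both steps (medians 5.29 and 2.11). Which cells carried Nes in the higher gates cannot be told from bulk libraries.

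**Figure D2:**
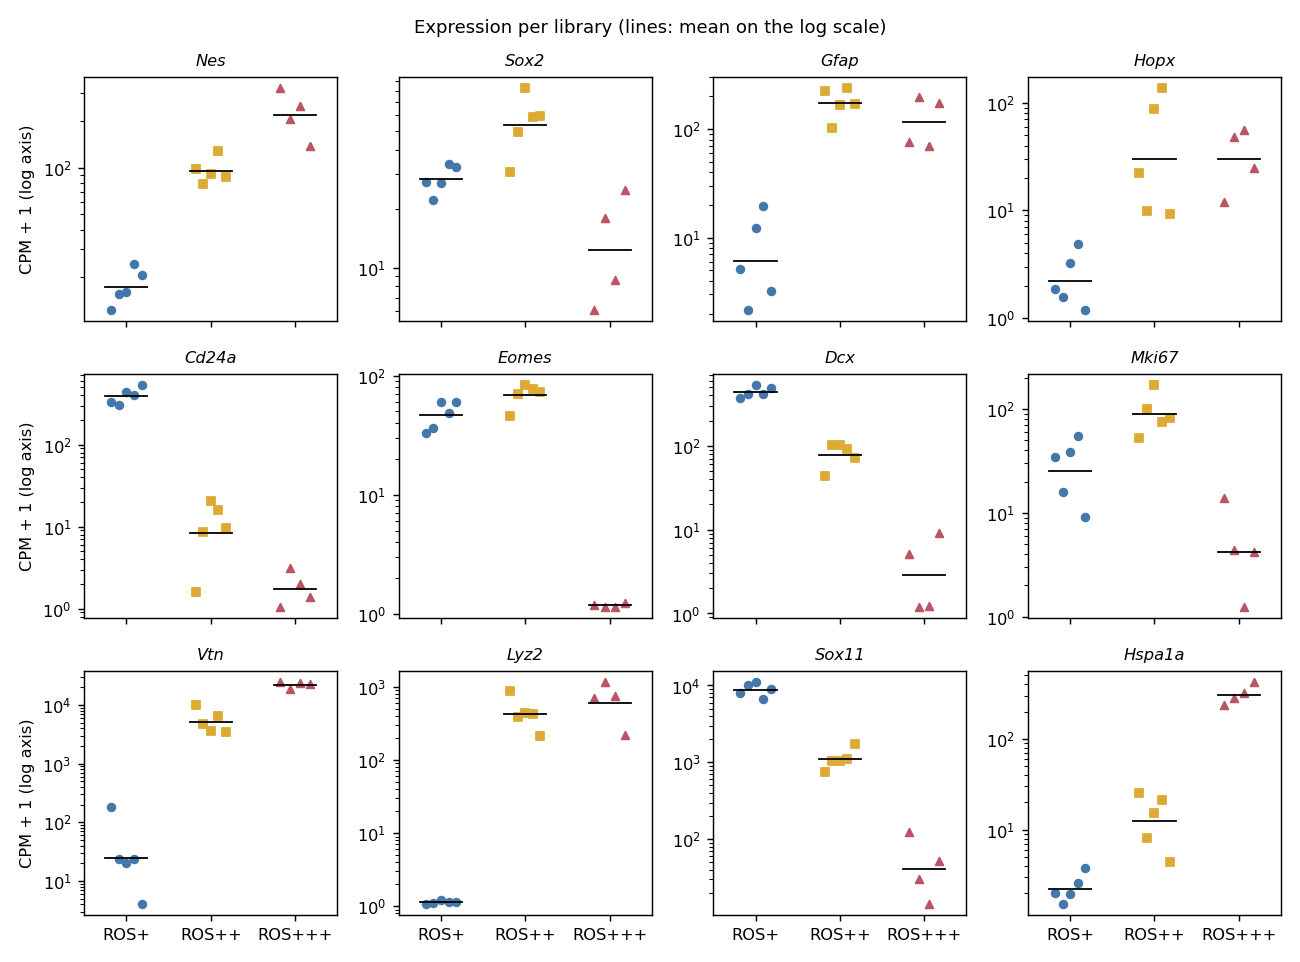
CPM + 1 on a log axis for 12 genes in each of the 14 libraries (points, by ROS class), with lines at the class mean on the log scale. Nes and Vtn step upward with the gate, Dcx and Sox11 step downward, and Mki67 peaks in ROS++.

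ROS++ cells differed from ROS+ cells by more transcripts of stem cell, astrocyte, mural cell and macrophage genes, more cell cycle transcripts, and fewer transcripts of the neuronal lineage. Of 15102 genes, 4476 (29.6%) passed the limma test, 2475 higher and 2001 lower in ROS++, or 55.3% higher. Changes of at least 2-fold numbered 1807 up and 969 down. In 3476 genes (23.0%) the libraries of both classes did not overlap, against 0.794% by chance. Largest among the non-overlapping gains was Lyz2, the lysozyme of macrophages (chromosome 10, 117277331 to 117282321, ENSMUSG00000069516), from 0.133 ± 0.0558 to 465 ± 242 CPM (8.54 ± 0.37, adjusted p = 7.76e-11). It was followed by the macrophage chemokine Ccl7 (8.01 ± 1.44), the secreted phosphoprotein Spp1 (7.98 ± 1.17), the pericyte cation pump Atp13a5 (7.97 ± 0.55), vitronectin (Vtn, 7.71 ± 0.77, from 50.5 ± 75.1 to 5569.8 ± 2657 CPM), Cd14 (7.60 ± 0.67), the complement receptor C5ar1 (7.45 ± 0.58) and the calcium store protein Casq2 (7.41 ± 0.26). The call of Ccl7 ended in limma-voom (adjusted p = 0.26, range over all alternatives 4.2e-08 to 0.26). The largest falls were in the neuropeptide gene Gal, by 5.59 ± 0.45, in Cd24a, a surface marker of neuroblasts, by 5.56 ± 0.51 (from 404 ± 90.6 to 10.2 ± 7.22 CPM), and in the neuronal growth protein gene Stmn2, by 5.03 ± 0.73. Neurod6, Fam84a, Zfp385b, Adamts18 and Sema3c completed that group, with falls of 5.03, 4.95, 4.85, 4.84 and 4.52.

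Stem cell and astrocyte lists were higher in ROS++. Of the 29 radial glia-like stem cell genes, 26 rose, 1 fell and 2 did not pass (28 higher and 1 lower adjusted over the list alone), with a median change of 2.58 (camera adjusted p = 1.83e-18). The milk fat globule protein gene Mfge8 rose by 2.53 ± 0.14, Notch2 by 3.96 ± 0.26 and the acyl-CoA synthetase gene Acsbg1 by 3.77 ± 0.32. Among 20 mature astrocyte genes, 17 rose and 3 did not pass (19 higher adjusted over the list alone, median 2.73, camera adjusted p = 2.77e-13), led by Itih3 (4.56 ± 0.29), Mlc1 (5.98 ± 0.44) and the sodium pump subunit Atp1b2 (2.55 ± 0.19). Both lists kept their call with an estimated correlation, as did 7 more of the 19 lists that camera called with its preset one. Sox2 missed the threshold at 0.92 ± 0.34 (adjusted p = 0.0504) and passed it under some alternatives (range 0.0033 to 0.13).

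Neuronal genes were lower in ROS++. Among 24 neuronal commitment genes, 19 fell and 1 rose (2 higher and 19 lower adjusted over the list alone, median -2.31, camera adjusted p = 3.21e-10), a call that held with an estimated correlation. The bHLH factor genes Neurod2, Neurod1 and Neurod6 fell by 4.29 ± 0.31, 4.21 ± 0.37 and 5.03 ± 0.50, and Dcx by 2.49 ± 0.46 (adjusted p = 0.000736). Eomes, of the same list, stood at 0.57 ± 0.25 (adjusted p = 0.10, not passed), and passed in limma-voom (adjusted p = 0.018) and without ROS++ replicate 1 (0.048, range 0.018 to 0.24). Of 16 mature neuron genes, 9 fell, led by the glutamate receptor gene Grin2b (2.48 ± 0.25), Rbfox3 (2.70 ± 0.37) and Camk2b (2.63 ± 0.42), and 1 rose (1 higher and 9 lower adjusted over the list alone, median -1.52, camera adjusted p = 0.000228). That call was lost, with adjusted p = 0.116 with an estimated correlation.

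Cell cycle transcripts were higher in ROS++ than in ROS+. Of 40 genes, 25 rose and none fell (32 higher and 1 lower adjusted over the list alone, median 1.54, camera adjusted p = 3.02e-08, and adjusted p = 0.175 with an estimated correlation). The chromatin protein gene Hmgb2 rose by 1.39 ± 0.18, the replicative helicase gene Mcm3 by 1.41 ± 0.24 and the polymerase clamp gene Pcna by 0.87 ± 0.16. Mki67 rose by 1.82 ± 0.56 (adjusted p = 0.0215), a call that ended without ROS+ replicate 2 (adjusted p = 0.056), without ROS+ replicate 5 (0.061), without ROS++ replicate 3 (0.055) and with the log2 values as deposited (0.093), over a range of 0.0029 to 0.093 in all alternatives. The 23 genes of cyclin-dependent kinase inhibitors and quiescence went both ways, 7 up and 5 down (7 higher and 5 lower adjusted over the list alone, median 0.26, camera adjusted p = 0.482). Within them Nfix fell by 1.91 ± 0.22, while the thioredoxin inhibitor gene Txnip rose by 1.83 ± 0.24 and Bmpr1a by 1.00 ± 0.14.

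Markers of other cell types moved with the gate. All 19 mural (pericyte and smooth muscle) genes rose (19 adjusted over the list alone), with a median of 5.29 (camera adjusted p = 6.29e-23), among them the potassium channel subunit gene Abcc9 (6.49 ± 0.34), Anpep (5.09 ± 0.32) and P2ry14 (3.91 ± 0.23). Of 24 microglia and macrophage genes, 23 rose (23 adjusted over the list alone, median 5.23, camera adjusted p = 2.36e-21). After Lyz2 came the cathepsin gene Ctss (6.32 ± 0.34) and the signalling adaptor gene Tyrobp (6.14 ± 0.33). Both calls held with an estimated correlation. In the leptomeningeal fibroblast list 8 of 12 genes rose, with Igf2 (4.64 ± 0.37) and Ogn (3.68 ± 0.37) first (10 higher adjusted over the list alone, median 3.30, camera adjusted p = 5.92e-06, and adjusted p = 0.0828 with an estimated correlation). The myelinating oligodendrocyte list had 10 of 19 genes higher, such as transferrin (Trf, 3.06 ± 0.42) and Opalin (4.55 ± 0.77), with a median of 1.42 (10 higher adjusted over the list alone, camera adjusted p = 2.12e-05, and adjusted p = 0.262 with an estimated correlation). Endothelial, oligodendrocyte precursor, and ependymal and choroid plexus lists were not called (camera adjusted p = 0.416, 0.641 and 0.577, medians 0.03, 0.01 and 1.14). Their members higher and lower numbered 4 and 1 of 22, 1 and 0 of 20, and 2 and 1 of 5 (4 and 0, 1 and 0, 2 and 1 adjusted over the list alone), with the endothelial adhesion gene Esam at 3.59 ± 0.30, the proteoglycan gene Cspg4 at 0.65 ± 0.13 and Rarres2 at 5.28 ± 0.39. None of the 3 erythroid genes measured passed.

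**Figure D3:**
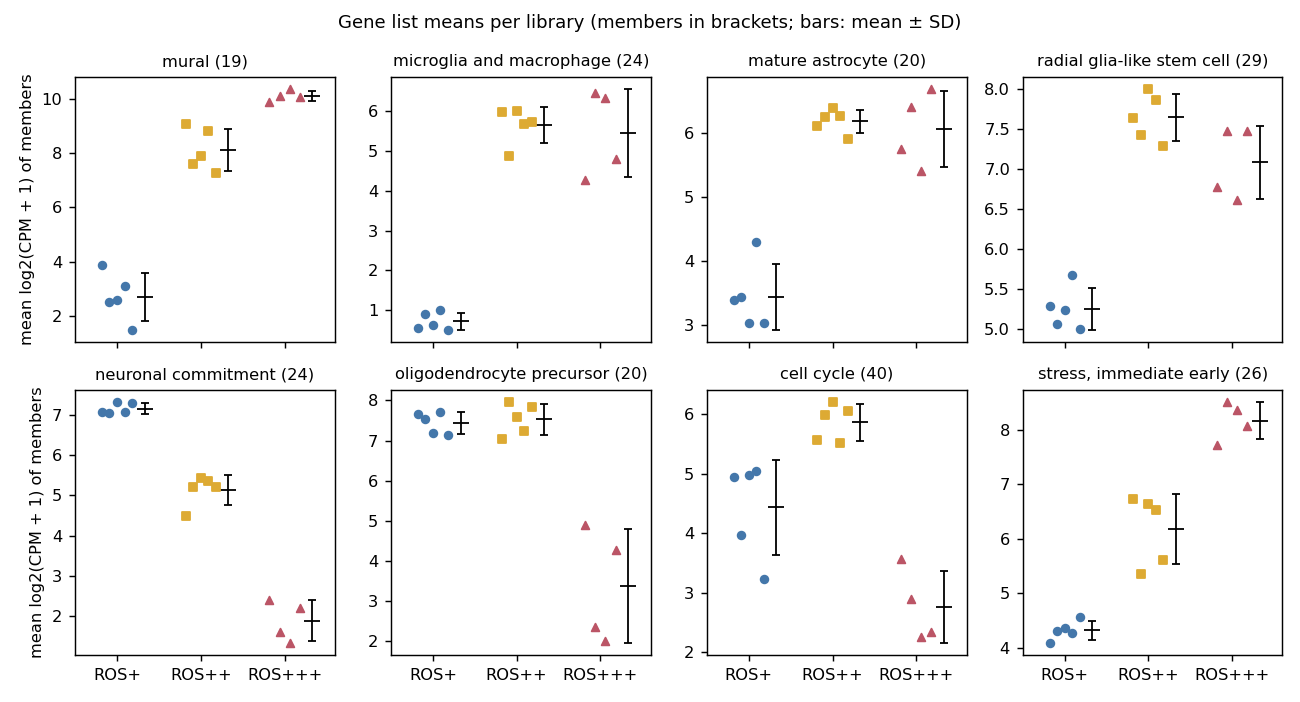
Mean log2(CPM + 1) over the members of 8 gene lists in each of the 14 libraries (points), with bars at the class mean ± SD for ROS+, ROS++ and ROS+++. Mural means climb with the gate, neuronal commitment means decline, and cell cycle means are highest in ROS++.

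Genes of oxidant handling were mostly higher in ROS++, in the same libraries as the mural and macrophage markers. Of 42 antioxidant defence and NRF2 target genes, 23 rose and 2 fell (25 higher and 2 lower adjusted over the list alone, median 0.54, camera adjusted p = 1.87e-08, held with an estimated correlation). The peroxidase gene Gpx8 rose by 3.02 ± 0.17, extracellular superoxide dismutase (Sod3) by 4.97 ± 0.32 and the glutathione transferase gene Gstm1 by 2.22 ± 0.17. Oxidant producers had 11 of 19 members higher and 0 lower (12 higher and 0 lower adjusted over the list alone, median 1.51, camera adjusted p = 4.95e-06, and adjusted p = 0.0643 with an estimated correlation). Subunits of the phagocyte NADPH oxidase led them. Cybb, its catalytic subunit (chromosome X, 9435252 to 9487771, ENSMUSG00000015340), went from 0.117 ± 0.0937 to 39.9 ± 15.6 CPM (5.13 ± 0.27, or 8.10 on the deposited scale), and Cyba rose by 4.48 ± 0.32. The interferon response list had 16 of 22 genes higher, including B2m (1.64 ± 0.17), Ifitm3 (3.19 ± 0.34) and H2-K1 (2.15 ± 0.26, whose reads are uncertain because H2-D1 is nearly identical), with a median of 1.66 (17 higher adjusted over the list alone, camera adjusted p = 8.29e-08, held with an estimated correlation). In the Notch list 9 of 23 genes rose and 2 fell (10 higher and 2 lower adjusted over the list alone, median 0.43, camera adjusted p = 0.000439, held with an estimated correlation). Its leading members were Notch2, Notch3 (4.81 ± 0.36) and Heyl (4.86 ± 0.40), and Notch3 also belongs to the mural list.

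Fatty acid oxidation had 12 of 29 genes higher, led by the thiolase gene Acaa2 (2.61 ± 0.21), with a median of 0.47 (12 higher adjusted over the list alone, camera adjusted p = 0.000967, held with an estimated correlation). Glycolysis had 6 of 23 genes up and 2 down, with Aldoc at 3.02 ± 0.29 and Aldoa at 1.02 ± 0.12 (7 higher and 3 lower adjusted over the list alone, median 0.32, camera adjusted p = 0.0134, and adjusted p = 0.116 with an estimated correlation). Aldoc is also a radial glia-like list member. Lipogenesis and cholesterol synthesis was not called (6 of 29 up and 1 down, 6 higher and 1 lower adjusted over the list alone, median 0.17, camera adjusted p = 0.416), although Thrsp, an activator of lipogenesis shared with the radial glia-like list, rose by 2.86 ± 0.28. Nuclear-encoded respiratory chain genes had 23 of 80 higher, led by the mural gene Ndufa4l2 (6.15 ± 0.54), with a median of 0.22 (23 higher adjusted over the list alone, camera adjusted p = 7.45e-05, and adjusted p = 0.295 with an estimated correlation). All 7 mitochondrially encoded protein genes rose, such as mt-Nd4 (0.60 ± 0.09) and mt-Nd6 (1.06 ± 0.17, which overlaps mt-Nd5 on the other strand and cannot be separated without strand), with a median of 0.60 (7 adjusted over the list alone, camera adjusted p = 5.61e-05, and adjusted p = 0.158 with an estimated correlation). Ribosomal protein genes were slightly lower, 24 of 81 falling and 1 rising (1 higher and 26 lower adjusted over the list alone, median -0.18, camera adjusted p = 1.86e-05, and adjusted p = 0.366 with an estimated correlation), among them Rps3 (fell by 0.50 ± 0.08), and their many processed pseudogenes make single values uncertain. These median directions held under all scalings.

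The dissociation stress and immediate early list had 17 of 26 genes higher and 2 lower in ROS++ (19 higher and 2 lower adjusted over the list alone, median 1.38, camera adjusted p = 1.56e-08, and adjusted p = 0.141 with an estimated correlation). The chemokine gene Ccl3 rose by 6.52 ± 0.61, the phosphatase gene Dusp1 by 2.55 ± 0.26 and Ier3 by 2.46 ± 0.27. Ccl3 lost its call in limma-voom (adjusted p = 0.058, range 1.5e-08 to 0.058). The p53 and apoptosis list (3 of 24 up and 3 down, 3 higher and 3 lower adjusted over the list alone, median 0.03) and the unfolded protein response list (5 of 22 up and 0 down, 4 higher and 0 lower adjusted over the list alone, median 0.19) were not called (camera adjusted p = 0.799 and 0.302). Perp, a membrane protein gene of the p53 list, rose by 4.94 ± 0.28, and the chaperone gene Hsp90b1 rose by 0.47 ± 0.09.

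ROS+++ cells differed from ROS+ cells by very high mural transcripts, high immediate early and macrophage transcripts, and near absence of neuronal precursor transcripts. The limma test called 8947 genes (59.2%), 2904 higher and 6043 lower, with 2388 up and 4234 down by at least 2-fold. Libraries did not overlap in 7553 genes (50.01%), against 1.59% by chance. The share of calls that were higher was 32.5% with library totals, 50.7% with relative log expression factors, 43.9% with upper-quartile factors and 48.0% with TMM factors. Those factors raised the median change of all genes, which was -0.44, by 0.40, 0.27 and 0.34. Changes below remain relative to library totals. Among the largest gains were the mural list members Vtn, Atp13a5 and Higd1b. Vtn (chromosome 11, 78499091 to 78502324, ENSMUSG00000017344) went from 50.5 ± 75.1 to 22247 ± 2489 CPM (9.82 ± 0.82, adjusted p = 8.90e-07) and Atp13a5 from 5.65 ± 5.69 to 5232 ± 569.8 CPM (10.07 ± 0.58). Casq2 (9.86), Spp1 (9.84), the ADP-ribosyltransferase gene Art3 (9.38), the amino acid transporter gene Slc6a20a (9.30) and the pericyte gene Higd1b (9.14) rose nearly as much. Among the deepest falls were members of the neuronal commitment list. Neurod1 fell by 9.09 ± 0.39, from 1538 ± 257 to 2.498 ± 2.903 CPM, and the calcium buffer gene Calb2 by 8.68 ± 0.74. Sox11 (chromosome 12, 27334264 to 27342574, ENSMUSG00000063632) fell by 7.76 ± 0.48, from 8984 ± 1702 to 54.2 ± 48.6 CPM. Cd24a, Neurod6, Dcx, Stmn2 and the neuronal tubulin gene Tubb3 fell by 7.83, 7.39, 7.26, 7.07 and 7.02.

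None of the 19 lists that camera called between ROS+++ and ROS+ kept its call with an estimated correlation, and those p-values follow each list. All 19 mural genes rose (median 7.23, camera adjusted p = 7.07e-20, and adjusted p = 0.0532 with an estimated correlation), with P2ry14, Abcc9 and Anpep at 6.12 ± 0.25, 8.47 ± 0.37 and 7.001 ± 0.34. In the microglia and macrophage list 23 of 24 genes rose, led by Lyz2 (9.08 ± 0.39) and Ctss (6.97 ± 0.36), with a median of 4.97 (camera adjusted p = 2.13e-15, and adjusted p = 0.0532 with an estimated correlation). Leptomeningeal fibroblast genes had 8 of 12 higher, with Igf2 at 6.50 ± 0.39 (median 3.87, camera adjusted p = 9.00e-06, and adjusted p = 0.0895 with an estimated correlation). Of 22 endothelial genes 9 rose and 1 fell, with Esam and the sialomucin gene Emcn at 5.74 ± 0.32 and 4.58 ± 0.40 (median 0.62, camera adjusted p = 0.000686, and adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone, 19 mural, 23 macrophage, 8 leptomeningeal and 9 endothelial genes were higher and 1 endothelial gene was lower.

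Stem cell and astrocyte lists stayed above their ROS+ level in ROS+++, but bulk libraries cannot tell if mural cells carried these transcripts. Radial glia-like genes had 21 of 29 higher and 3 lower (median 1.89, camera adjusted p = 2.73e-09, and adjusted p = 0.0895 with an estimated correlation). Mfge8 and Sparcl1 rose by 3.68 ± 0.15 and 2.74 ± 0.15 while the BMP target Id2 fell by 2.59 ± 0.15. Astrocyte genes had 18 of 20 higher and 1 lower (median 2.87, camera adjusted p = 3.66e-09, and adjusted p = 0.0895 with an estimated correlation). Atp1b2 rose by 3.93 ± 0.21 and the calcium-binding protein gene S100b fell by 3.83 ± 0.29. Adjusted over the list alone, 21 and 3 radial glia-like and 18 and 1 astrocyte genes were higher and lower. Nes, Gfap and Hopx rose by 3.67 ± 0.24, 4.24 ± 0.55 and 3.75 ± 0.74. Sox2 fell by 1.19 ± 0.36 (adjusted p = 0.00899), a call that ended with relative log expression factors (-0.78, adjusted p = 0.070) and TMM factors (0.052, range over all alternatives 0.0013 to 0.070).

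The neuronal commitment, oligodendrocyte precursor and cell cycle lists were lower in ROS+++ than in ROS+. Of 24 neuronal commitment genes 23 fell and 0 rose (median -5.12, camera adjusted p = 2.11e-12, and adjusted p = 0.0532 with an estimated correlation), with Eomes at -5.29 ± 0.27 and Igfbpl1 at -6.12 ± 0.31. Mature neuron genes had 11 of 16 lower and 2 higher, Snap25 falling by 4.87 ± 0.41 and Chn1 rising by 2.12 ± 0.17 (median -2.68, camera adjusted p = 0.0281, and adjusted p = 0.336 with an estimated correlation). In the oligodendrocyte precursor list 19 of 20 genes fell and 1, Cspg4, rose, which pericytes also express (median -4.15, camera adjusted p = 4.49e-06, and adjusted p = 0.336 with an estimated correlation). The lineage factor gene Sox10 fell by 4.03 ± 0.31 and Enpp6 by 6.41 ± 0.47. Cell cycle genes had 25 of 40 lower and none higher, led by Mcm7 (-2.59 ± 0.18) and Mcm5 (-2.37 ± 0.26), and Mki67 fell by 2.58 ± 0.60 (list median -1.74, camera adjusted p = 0.00189, and adjusted p = 0.426 with an estimated correlation). Adjusted over the list alone, 23 commitment, 11 mature neuron, 19 oligodendrocyte precursor and 26 cell cycle genes were lower. The kinase inhibitor and quiescence list was not called (7 up and 6 down, 7 higher and 6 lower adjusted over the list alone, median 0.22, camera adjusted p = 0.0512), and several alternatives called it higher (range 0.021 to 0.35). Under relative log expression, upper-quartile and TMM factors its medians were 0.65, 0.51 and 0.59, with 11 up and 2 down under the first. Nfix fell by 4.65 ± 0.24 and the antiproliferative gene Btg1 rose by 2.14 ± 0.18. Myelinating genes went both ways (7 up, 7 down, 7 higher and 7 lower adjusted over the list alone, median 0.13, mean 0.11, camera adjusted p = 0.406), with Ugt8a at -3.51 ± 0.37 and Trf at 2.83 ± 0.45.

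Stress, immune and oxidant lists were higher in ROS+++ than in ROS+, alongside the mural and macrophage markers. In the dissociation stress and immediate early list 25 of 26 genes rose and none fell (25 higher adjusted over the list alone, median 3.68, camera adjusted p = 4.57e-18, and adjusted p = 0.0532 with an estimated correlation). Btg2 and the AP-1 gene Jun rose by 3.41 ± 0.19 and 3.66 ± 0.22. Interferon response genes had 16 of 22 higher and 1 lower (16 higher and 1 lower adjusted over the list alone), with B2m at 2.31 ± 0.18 and Ifitm3 at 4.84 ± 0.36 (median 2.09, camera adjusted p = 6.43e-08, and adjusted p = 0.0532 with an estimated correlation). Oxidant producers had 12 of 19 higher and 1 lower (12 higher and 1 lower adjusted over the list alone, median 2.35, camera adjusted p = 5.74e-06, and adjusted p = 0.0828 with an estimated correlation). Cybb reached 87.7 ± 15.4 CPM (6.30 ± 0.29) and Cyba 239.8 ± 39.4 CPM (5.54 ± 0.34). Of 42 antioxidant genes 20 rose and 7 fell (21 higher and 7 lower adjusted over the list alone, median 0.36, or 0.79, 0.65 and 0.73 with relative log expression, upper-quartile and TMM factors), with Gpx8, Sod3 and Gpx1 at 4.51 ± 0.18, 7.22 ± 0.34 and 2.20 ± 0.14 (camera adjusted p = 5.37e-05, and adjusted p = 0.0532 with an estimated correlation). Notch genes had 9 of 23 higher and 8 lower (9 higher and 8 lower adjusted over the list alone, median 0.06, -0.00562 without ROS+++ replicate 1 and -0.0358 without ROS+++ replicate 3, camera adjusted p = 0.0209, and adjusted p = 0.0895 with an estimated correlation), with Notch3 at 7.23 ± 0.38 and Hes1 at 4.21 ± 0.30. The p53 list was not called (8 up, 9 down, 8 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.409), and its median of -0.39 differed in sign from its mean of 0.15 and from the median of 0.02 with relative log expression factors. Perp rose by 7.18 ± 0.30, and the BH3 domain gene Bid fell by 3.76 ± 0.25. The unfolded protein response list was not called either (6 up, 8 down, 6 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.378), its median of -0.02 turning to 0.39, 0.26 and 0.33 with those factors, with Pdia6 at -1.10 ± 0.12 and Ppp1r15a at 2.62 ± 0.29.

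Energy metabolism lists depended on the scaling in this comparison. Fatty acid oxidation had 12 of 29 genes higher and 5 lower (12 higher and 5 lower adjusted over the list alone), with Acaa2 at 4.10 ± 0.23 and Hadh at 1.42 ± 0.14 (median 0.56, or 1.00, 0.85 and 0.94 with relative log expression, upper-quartile and TMM factors, camera adjusted p = 0.00185, and adjusted p = 0.0532 with an estimated correlation). Glycolysis was called higher (9 of 23 up, 3 down, 9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0118, and adjusted p = 0.104 with an estimated correlation). Its median was -0.05, against a mean of 0.26 and medians of 0.39, 0.24 and 0.32 with those factors, and Aldoa rose by 1.81 ± 0.12. Respiratory chain genes had 19 of 80 higher and 6 lower (18 higher and 5 lower adjusted over the list alone), or 61 and 1 with relative log expression factors, with Ndufa4 at -2.32 ± 0.18 and Ndufa4l2 at 8.55 ± 0.57 (median 0.15, or 0.59, 0.45 and 0.53 with those factors, camera adjusted p = 0.00125, and adjusted p = 0.397 with an estimated correlation). The mitochondrially encoded list was not called (1 up, 1 down, 1 higher and 1 lower adjusted over the list alone, median 0.18, camera adjusted p = 0.236) but was called higher with those factors (medians 0.62, 0.48 and 0.56) and without ROS+++ replicate 3 (adjusted p = 0.034, range 0.0099 to 0.60). mt-Co1 fell by 0.35 ± 0.11 with library totals but stood at 0.0902, -0.0553 and 0.0274 with those factors. Lipogenesis and cholesterol synthesis had 4 of 29 genes higher and 15 lower, among them Acaca (-2.11 ± 0.23) and Scd2 (-1.22 ± 0.14), and was not called (4 higher and 15 lower adjusted over the list alone, median -0.49, or -0.05, -0.19 and -0.11 with those factors, camera adjusted p = 0.378). Ribosomal protein genes had 70 of 81 lower and 1 higher (1 higher and 71 lower adjusted over the list alone), Rpl4 falling by 0.85 ± 0.07 (median -0.66, or -0.22, -0.36 and -0.28 with those factors, camera adjusted p = 5.54e-10, and adjusted p = 0.239 with an estimated correlation). The ependymal and choroid plexus list was not called (2 of 5 up and 2 down, 2 higher and 2 lower adjusted over the list alone, median 1.19, camera adjusted p = 0.378), with Rarres2 at 7.38 ± 0.42 and Hydin at -2.66 ± 0.32. Of the 3 erythroid genes tested Bpgm fell by 1.97 ± 0.25 and Fech rose by 0.91 ± 0.38 (adjusted p = 0.0462). The call of Fech ended in 11 alternatives (range 0.0020 to 0.12). They were the deposited scale, the block for library numbers, and leaving out ROS+ replicate 1, 2, 3 or 4, ROS++ replicate 2 or any 1 ROS+++ library (0.79 to 1.06 leaving out libraries). Alas2, the haem synthesis gene of red cells, stood at 0.31 ± 0.83 (adjusted p = 0.769).

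From ROS++ to ROS+++, the dissociation stress and immediate early list rose, the mural list rose further, and cell cycle, oligodendrocyte precursor and neuronal commitment lists fell. The limma test called 5898 genes (39.1%), 1493 higher and 4405 lower, with 1130 up and 2939 down by at least 2-fold. Libraries did not overlap in 4076 genes (27.0%), against 1.59% by chance. The share of calls that were higher was 25.3% with library totals, 52.2% with relative log expression factors, 42.4% with upper-quartile factors and 46.4% with TMM factors. Those factors raised the median change of all genes, -0.34 with library totals, by 0.37, 0.25 and 0.29. The largest gain was in the inducible heat shock gene Hspa1a (chromosome 17, 34969190 to 34972156, ENSMUSG00000091971), from 13.8 ± 8.78 to 314 ± 80.4 CPM (4.64 ± 0.44, adjusted p = 4.72e-07). It was followed by its co-chaperone gene Dnajb1 (4.02 ± 0.33, from 60.9 ± 23.6 to 958 ± 203 CPM) and by Hspa1b (3.64 ± 0.41), a near-identical copy of Hspa1a, so that the split of reads between this pair is uncertain. The kinase gene Nuak2, the stress gene Gadd45b, the AP-1 gene Fosb, the transcription factor gene Snai1 and the immediate early gene Egr1 rose by 3.62, 3.61, 3.40, 3.21 and 3.10. The deepest falls were in Neu4, by 6.34 ± 0.70, in Vxn, by 6.25 ± 0.58, and in Gpr17, a receptor gene of differentiating oligodendrocyte precursors (chromosome 18, 31942997 to 31949636, ENSMUSG00000052229), by 6.21 ± 0.87, from 607 ± 191 to 17.6 ± 20.8 CPM. The mitotic kinase gene Pbk fell by 5.96 ± 0.75, a call that ended in limma-voom (adjusted p = 0.051, range 3.4e-06 to 0.051). Enpp6 fell by 5.93, Eomes fell by 5.86, and Lhfpl3 and Olfm2 fell by 5.68 and 5.53.

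None of the 13 lists called between ROS+++ and ROS++ held with an estimated correlation. In the dissociation stress and immediate early list 21 of 26 genes rose and none fell (24 higher adjusted over the list alone, median 1.94, camera adjusted p = 1.70e-20, and adjusted p = 0.112 with an estimated correlation). The constitutive chaperone gene Hspa8 rose by 1.02 ± 0.09 and Jun by 2.44 ± 0.22. Mural genes rose in the same libraries, 15 of 19 passing (16 adjusted over the list alone) with a median of 2.11 (camera adjusted p = 4.01e-13, and adjusted p = 0.248 with an estimated correlation), P2ry14 and Gper1 by 2.21 ± 0.25 and 2.42 ± 0.32. Endothelial genes had 6 of 22 higher and 1 lower (6 higher and 1 lower adjusted over the list alone), with Esam at 2.15 ± 0.32 (median 1.05, but 0.47 without ROS++ replicate 5, camera adjusted p = 1.33e-05, and adjusted p = 0.356 with an estimated correlation). Leptomeningeal genes had 5 of 12 higher and none lower (5 higher and 1 lower adjusted over the list alone, median 0.86, camera adjusted p = 0.00680, and adjusted p = 0.356 with an estimated correlation), Col1a2 by 1.88 ± 0.45. Interferon genes had 5 of 22 higher and 1 lower (5 higher and 1 lower adjusted over the list alone), Ifitm3 by 1.65 ± 0.36 (median 0.53, but 0.34 without ROS++ replicate 5, camera adjusted p = 0.00269, and adjusted p = 0.356 with an estimated correlation).

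The microglia and macrophage list was not called (1 of 24 higher and none lower, 1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.135). Its median was -0.20, against 0.19, 0.06 and 0.11 with relative log expression, upper-quartile and TMM factors, and camera called it higher without ROS+++ replicate 1 (adjusted p = 0.024) or replicate 4 (0.012, range over all alternatives 0.012 to 1.0). The leukocyte phosphatase gene Ptprc rose by 1.66 ± 0.41, lost on the deposited scale (adjusted p = 0.11, range 0.00066 to 0.11), and the scavenger receptor gene Cd163 stood at -1.79 ± 0.75 (adjusted p = 0.0669, not passed). Cd163 passed without ROS+++ replicate 2 (-2.60, adjusted p = 0.0067), without replicate 3 (-2.25, adjusted p = 0.036) and with the library number as covariate (adjusted p = 0.049, range 0.0067 to 0.42). Oxidant producers were called higher, with 3 of 19 genes up and none down (3 higher adjusted over the list alone, median 0.22, camera adjusted p = 0.0139, and adjusted p = 0.356 with an estimated correlation). That median was 0.0873 without ROS+++ replicate 1, 0.0517 without ROS++ replicate 5 and 0.40 without ROS++ replicate 1. Without ROS+++ replicate 1 and ROS++ replicate 5 together it was -0.00369 and the call was lost (adjusted p = 0.069, range 0.0023 to 0.36), as it was in fry (0.18). Fry also lost the calls of the endothelial (adjusted p = 0.059, range 1.2e-07 to 0.36), leptomeningeal (0.10, range 0.00017 to 0.36) and interferon response lists (0.10, range 0.00052 to 0.36). Cybb rose by 1.17 ± 0.29 and lost its call on the deposited scale (adjusted p = 0.076, range 0.00024 to 0.076). The antioxidant list was not called (4 of 42 up, 12 down, 4 higher and 12 lower adjusted over the list alone, median -0.11, mean -0.20, camera adjusted p = 0.406), and its median turned to 0.31, 0.17 and 0.23 with those factors. Prdx2 fell by 1.00 ± 0.11 while Gpx8 rose by 1.49 ± 0.18.

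Every cell cycle gene of the list, 40 of 40, fell from ROS++ to ROS+++ (also 40 adjusted over the list alone, and 39 with relative log expression factors), with a median of -2.98 (camera adjusted p = 4.37e-14, and adjusted p = 0.248 with an estimated correlation). Mcm5 fell by 3.35 ± 0.26, the ribonucleotide reductase gene Rrm1 by 1.78 ± 0.15 and Mki67 by 4.40 ± 0.60. Oligodendrocyte precursor genes had 19 of 20 lower and 1 higher (1 higher and 19 lower adjusted over the list alone), Sox10 falling by 4.35 ± 0.31 while Enpp6 fell by 5.93 ± 0.47 (median -4.41, camera adjusted p = 2.83e-10, and adjusted p = 0.356 with an estimated correlation). Neuronal commitment genes had 21 of 24 lower (22 adjusted over the list alone), where Eomes fell by 5.86 ± 0.27 and the microtubule regulator gene Stmn1 by 3.18 ± 0.25 (median -3.44, camera adjusted p = 4.48e-12, and adjusted p = 0.112 with an estimated correlation). Myelinating genes had 11 of 19 lower and 1 higher (1 higher and 11 lower adjusted over the list alone), Ugt8a falling by 4.03 ± 0.37 (median -2.10, camera adjusted p = 0.0163, and adjusted p = 0.562 with an estimated correlation). Without ROS++ replicate 1 that list was no longer called (adjusted p = 0.071, range 0.00095 to 0.56). Mature neuron, radial glia-like and astrocyte lists were not called (camera adjusted p = 0.571, 0.507 and 0.316). Higher and lower members numbered 2 and 7, 4 and 11, and 1 and 3 (2 and 8, 4 and 12, and 1 and 3 adjusted over the list alone), with medians of -0.73, -0.58 and -0.06, the last of which turned to 0.35, 0.21 and 0.27 with the other scalings. Within them Snap25 fell by 3.11 ± 0.41, Id2 fell by 1.40 ± 0.15, Fabp7, a radial glial lipid carrier gene, fell by 1.74 ± 0.20, and S100b fell by 4.12 ± 0.29, while Mfge8 rose by 1.15 ± 0.15. Sox2 and Dcx fell by 2.11 ± 0.36 and 4.77 ± 0.49. Gfap and Hopx stood at -0.58 ± 0.55 and -0.001 ± 0.74 (adjusted p = 0.431 and 0.999).

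Lipogenesis and cholesterol synthesis was called lower in ROS+++ than in ROS++ with library totals, 13 of 29 genes falling and 1 rising (1 higher and 13 lower adjusted over the list alone, median -0.48, camera adjusted p = 0.0312, and adjusted p = 0.356 with an estimated correlation). The desaturase gene Scd2 fell by 1.68 ± 0.14, the fatty acid synthase gene Fasn by 1.87 ± 0.25 and the carboxylase gene Acaca by 1.72 ± 0.23. With relative log expression, upper-quartile and TMM factors the list median was -0.16, -0.26 and -0.22 and the call was lost, as it was without ROS++ replicate 1 (adjusted p = 0.069, range 2.5e-05 to 0.36). Ribosomal protein genes had 64 of 81 lower and 1 higher (1 higher and 67 lower adjusted over the list alone, camera adjusted p = 2.83e-10, and adjusted p = 0.356 with an estimated correlation), Rps26 falling by 0.96 ± 0.12. Their median of -0.51 became -0.09, -0.23 and -0.17 with those factors, the first no longer called (range of adjusted p 2.9e-11 to 0.36). Mitochondrially encoded genes had 6 of 7 lower and none higher (0 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0312, and adjusted p = 0.463 with an estimated correlation), mt-Co1 falling by 0.90 ± 0.11. Their median of -0.40 became 0.01, -0.12 and -0.07 with those factors, none of them called, and the call also ended without ROS++ replicate 1 (adjusted p = 0.069) or ROS+++ replicate 3 (0.065, range 0.0024 to 0.51). Respiratory chain genes were not called (3 of 80 up, 13 down, 3 higher and 10 lower adjusted over the list alone, median -0.06, mean -0.05, camera adjusted p = 0.376) and were called higher with those factors (medians 0.35, 0.22 and 0.27, and 36 genes up and 1 down with the first). Ndufa4 fell by 2.14 ± 0.18.

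Glycolysis (4 up, 6 down, 5 higher and 7 lower adjusted over the list alone, median 0.14, mean -0.10) and fatty acid oxidation (5 up, 4 down, 5 higher and 4 lower adjusted over the list alone, median -0.14, mean -0.02) were not called between ROS+++ and ROS++ (camera adjusted p = 0.135 and 0.135). The other scalings called both higher, with medians of 0.55, 0.42 and 0.47 and of 0.27, 0.13 and 0.19. Aldoa rose by 0.79 ± 0.12, while the lactate transporter gene Slc16a1 fell by 2.19 ± 0.41. Notch genes were not called (7 up, 8 down, 8 higher and 8 lower adjusted over the list alone, median -0.20, mean -0.24, or medians 0.15, 0.06 and 0.07 with the other scalings, camera adjusted p = 0.313), where the neuronal ligand gene Dner fell by 2.85 ± 0.38, the ligand gene Dll1 fell by 3.28 ± 0.44 and Notch3 rose by 2.43 ± 0.38. The p53 list (4 up, 6 down, 4 higher and 6 lower adjusted over the list alone, median -0.24, mean -0.10, or medians 0.09, -0.03 and 0.01) and the unfolded protein response list (3 up, 9 down, 3 higher and 9 lower adjusted over the list alone, median -0.32, mean -0.23, or medians 0.10, -0.04 and 0.01) were not called (camera adjusted p = 0.406 and 0.868). In them Bid fell by 2.38 ± 0.25, Perp rose by 2.24 ± 0.30, and Ppp1r15a, a stress-induced phosphatase subunit gene, rose by 2.43 ± 0.29. Kinase inhibitor and quiescence genes (5 up, 2 down, 5 higher and 2 lower adjusted over the list alone, median 0.02, mean -0.000, camera adjusted p = 0.0904) and the ependymal and choroid plexus list (1 up, 1 down, 1 higher and 1 lower adjusted over the list alone, median 0.30, camera adjusted p = 0.262) were not called, with Nfix falling by 2.74 ± 0.24 and Tekt1 by 2.11 ± 0.53. The other scalings called the kinase inhibitor list higher, with medians of 0.40, 0.27 and 0.32 (adjusted p = 0.039, 0.043 and 0.039), and it was called without ROS++ replicate 3 (adjusted p = 0.045, median 0.0920, range over all alternatives 0.039 to 0.93). Of the erythroid genes Bpgm fell by 1.74 ± 0.25. In this comparison camera pointed upward for the astrocyte, macrophage, antioxidant, glycolysis, fatty acid oxidation, Notch, p53, unfolded protein response, respiratory chain, and kinase inhibitor lists although their median or mean lay below 0. Camera sets a list against all other genes, whose median change was -0.34.

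Calls at both steps were also counted together. ROS++ stood above both other classes in 413 genes, 225 of them by at least 2-fold at both steps, and below both in 76 genes, 26 of them by that size. Another 824 genes rose at both steps (616 by at least 2-fold at each) and 815 fell at both (342). These counts share the ROS++ libraries. They rest on library totals, with which 25.3% of calls between ROS+++ and ROS++ were higher, against 52.2% with relative log expression factors. The balance between the patterns therefore depends on the scaling. Independent lists of the same sizes would share 722, 198, 245 and 584 genes in that order, and the highest count in 20 draws with unchanged classes was 0 for each pattern. Among the 40 cell cycle genes 25 were above both other classes.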

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

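The tests of vessel fragments, of the scaling of mural and macrophage genes, of the stress genes and of ROS++ as a mixture were chosen only after their results were seen. The splits of the libraries, the test of shared variation, the test of doubled DNA and the scaling of the cell cycle list were set before.

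Libraries standing far from the others of their class were looked for in the genes, list means and read totals the text reports. Of 549 groups of values, 30 held such a library, where chance gives about 1 in 20 groups, or 27.45. In ROS+ replicate 1 Spp1 stood at 105 (others 0.134 to 1.92) CPM, Cd14 at 0.909 (others 0.0446 to 0.144) and Col1a2 at 8.81 (others 1.69 to 2.81). The endothelial list mean was 4.54 (others 3.41 to 3.62) and Pf4 0.256 (others 0 to 0.04800) CPM in ROS+ replicate 4, and in ROS+ replicate 5 Rps26 was 376 (others 328 to 340.3) and Rgs5 10.7 (others 142 to 239) CPM. In ROS++ replicate 1 Eomes was low at 44.99 (others 69.4 to 82.1) CPM, as was the neuronal commitment mean at 4.49 (others 5.21 to 5.43). In ROS++ replicate 2 the macrophage list mean was low at 4.86 (others 5.67 to 6.001), and Gal at 4.400 (others 0 to 0.0511) and Hsp90b1 at 614 (others 525 to 541) CPM were high. ROS++ replicate 3 had the most reads of its class, 23454022 (others 18325361 to 19566863), and Cybb at 67.7 (others 30.1 to 34.6) CPM. In ROS++ replicate 5 Emcn was 13.9 (others 72.7 to 114), Hes1 21.6 (others 35.6 to 40.9) and Neurod6 0 (others 6.22 to 10.4) CPM.

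In ROS+++ replicate 1 Ndufa4l2 stood at 865 (others 1551 to 1695) CPM, Txnip at 306 (others 385 to 398) CPM and the myelinating list mean at 4.55 (others 4.82 to 4.86). Replicate 2 of that class had high Mcm3 (34.4 CPM, others 16.6 to 18.1) and Tekt1 (6.38 CPM, others 0 to 0.143). Replicate 3 had Nuak2 at 118 (others 61.4 to 65.4), Ndufa4 at 51.4 (others 88.4 to 91.1) and Hspb8 at 0.143 (others 17.8 to 26.4) CPM. Replicate 4 had the fewest reads, 12704227 (others 20376708 to 20998589), and red cell transcripts: Alas2 stood at 50.8 (others 0.143 to 1.18) CPM and the erythroid mean at 6.08 (others 3.64 to 3.98). Dusp1 at 291 (others 411 to 419) and Hydin at 0.315 (others 0.764 to 0.857) CPM were low there.

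Chance assignment is argued against for the gene counts, if the libraries are independent, which the labels do not state. The 100 include the real split, so 1 is the lowest possible. In each comparison 1 of 100 splits of the libraries, the real one, gave as many genes: 4476 in ROS++ versus ROS+ (highest other split 359), 8947 in ROS+++ versus ROS+ (5997), 5898 in ROS+++ versus ROS++ (4796) and 9294 for any difference (5257). Lists called numbered 19, 19 and 13, and 15, 5 and 18 of 100 splits called as many (highest others 20, 19 and 15). Splits that swap few libraries keep part of the real contrast, so chance stays open for lists.

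Mural transcripts rose at both steps of the ROS gate, and macrophage transcripts from ROS+ to ROS++ but not further as a list (median -0.20 from ROS++ to ROS+++), although all classes were sorted as GFP-positive, a gate that would remove GFP-negative cells of the vessel wall and blood. The mural list call from ROS++ to ROS+++ was lost in camera with an estimated correlation (adjusted p = 0.248). The most abundant genes of the mural list, Rgs5 and Vtn, averaged 149 ± 84.9 and 50.5 ± 75.1 CPM in ROS+ and 22325 ± 3125 and 22247 ± 2489 CPM in ROS+++, and the most abundant gene of the macrophage list, Lyz2, 0.133 and 716 ± 389 CPM. Whole vessel fragments are argued against by the endothelial list, whose upper quartile of change (1.75) lay below the mural lower quartile (6.09), and library scaling by medians of at least 5.18 for both lists under the other factors. Mural cells and macrophages in shares that differ between libraries predicted that members of each list vary together within classes. Over the 9 ROS++ and ROS+++ libraries they did (mean residual correlations 0.811 and 0.438, 95th percentiles of 1000 random lists 0.122 and 0.0639), and varied less with each other (0.179). The random lists were matched on mean expression only, and variation within classes cannot show why the lists rise between gates. This explanation therefore remains possible and is not decided. Whether Nestin-positive pericytes that truly carry GFP or cells beyond the gate brought them stays open, and ROS+ itself held 17 of 19 mural, 21 of 22 endothelial and 6 of 24 macrophage genes at 1 CPM or more.

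Transcripts of the dissociation stress and immediate early list were high in ROS+++, where 21 of the 26 genes were called above ROS++. The share of the ROS+++ excess over ROS+ already present in ROS++ was at most 7.66% for the 4 heat shock genes of the list left in this test (Dnajb1, Hspa8, Hspa1a and Hspa1b), against 21.2 to 28.8% (quartiles) for the mural genes. Hspa8 stood at -76.2%, since its mean in ROS++ lay below that in ROS+. All these shares divide class means, so the spread between libraries is not in them. On class means the cells that bring the mural transcripts did not carry these 4 in both gates alike, which says nothing of other heat shock genes such as Hsp90aa1 and Hspb8. Over the 25 genes of the list called above ROS+ the upper quartile, 30.6%, lay below the macrophage lower quartile of 65.1%. On class means this argues against the macrophages for the list as a set, but Ccl3 (73.5%) lay within the macrophage quartiles and Ccl4 (56.7%) was the next highest, so for these macrophages stay open. For the immediate early genes the median of 21.2% (quartiles 12.9 to 30.7%) lay just below the mural quartiles while the ranges between quartiles overlapped, so transcripts carried by the cells that bring the mural ones and a response of ROS+++ cells in general cannot be told apart. Longer handling of the ROS+++ sample before lysis could also have raised these 21 genes and cannot be told apart from a state of the cells, because no sorting or lysis times are given.

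Cell cycle transcripts were highest in ROS++. ROS++ as a mixture of ROS+ and ROS+++ cells is argued against, since 25 of the 40 genes were called above both other classes, and scaling to library totals likewise, since the list was called under the 3 other scalings in both comparisons with ROS++ (largest camera adjusted p = 4.45e-08), although with library totals neither call held with an estimated correlation (adjusted p = 0.175 and 0.248). More dye bound by cells with doubled DNA may contribute. The median rise from ROS+ was 1.83 for genes of G2 and mitosis and 0.87 for those of G1 and S phase, a difference of 0.96 where at least 1 was predicted, so this and a higher share of dividing cells cannot be told apart without DNA content per cell. The biological difference named by the sort, ROS content, remains open for all 3 patterns and untested.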

How the results depend on the processing

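Added only after the data were seen were the alternatives with TMM factors, with the deposited log2 values, with a residual principal component, with a block for sets of library numbers, with joint removal of ROS+++ replicate 1 and ROS++ replicate 5, and with camera on log2 CPM at a prior count of 2. The plan had named TMM factors, with edgeR on counts, and this camera setting for the main results, which used library totals and log2(CPM + 1) instead. DESeq2 and svaseq were planned and not run.

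Of 305 values of named genes, 270 kept their direction and their side of the threshold in every alternative run for them, and the other 35 changed in at least 1. The alternatives numbered 28, of which the strict filter left 287 of these values. Over 8522 values 51 lost the call, 45 gained it and 22 turned in direction. For lists the direction counted was that of the list test (camera or fry), not that of the median. Of 78 list results 18 kept this direction and their side of the threshold in every alternative run for them (31, the strict filter leaving 75), and 52 did so when the estimated correlation was left aside. Over 2415 values 59 lost the call, 41 gained it and 14 turned in this direction. List medians that changed sign with the scaling, as given above, are not counted as turned. The counts of called genes moved by less than 1.5 times in every alternative: 3634 to 5230 for ROS++ versus ROS+, 7915 to 9286 for ROS+++ versus ROS+, 4852 to 6240 for ROS+++ versus ROS++ and 8404 to 9582 for any difference. Lists called numbered 19, 19 and 13 in these comparisons, and with an estimated correlation 9, 0 and 0, and the cause was not tested. The balance of rises and falls between ROS+++ and ROS+ depends on the scaling, as given above.

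The labels name no animal, day or pair, but the library numbers repeat the order of the classes. They were cut into 5 sets wherever a number was skipped or a class came round again. Each set therefore holds at most 1 library per class by construction. Whether such a set is a pairing is not stated. Deviations from the class means correlated at -0.0222 to 0.231 (median 0.0842) in the 13 pairs within a set, over 0.1 in 3 of them, and at -0.150 to 0.161 between sets. Of 14 libraries 10 correlated best with a library of their own set, a hint from the data and not from the design. With these sets as a block (7 residual degrees of freedom) 4699, 9065 and 6134 genes were called in the 3 comparisons and 9397 for any difference, and every list kept its call. Of named genes Sox2 gained its call in ROS++ versus ROS+ and mt-Nd4 in ROS+++ versus ROS+, and Fech lost it in ROS+++ versus ROS+.

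The following gene values and list test directions turned, and except where said the cause was not tested. With relative log expression factors mt-Co1 stood at 0.0902 in ROS+++ versus ROS+ (TMM 0.0274) and mt-Cytb at 0.0135 in ROS+++ versus ROS++, since these factors shift every change of ROS+++ upward. Hopx in ROS+++ versus ROS++, never called, stood at 0.40, 0.27 and 0.32 with relative log expression, upper-quartile and TMM factors, 0.00938 with a pseudocount of 0.5, 0.0200 as deposited, and -0.43 to 0.54 leaving out libraries. Alas2, never called, stood at 0.0126 in ROS++ versus ROS+ with a pseudocount of 5 (-0.33 to 0.27 leaving out libraries), at -0.34 in limma-voom and -0.31 as deposited in ROS+++ versus ROS+ (-0.95 to 0.88), and at -0.22 in limma-voom in ROS+++ versus ROS++ (-0.87 to 0.96). Among ROS+++ libraries replicate 4 held nearly all Alas2 reads. The p53 list median in ROS++ versus ROS+ was 0.0289 with the strict filter, where 22 of 24 members were left and camera's direction turned, and -0.13 to 0.0753 leaving out libraries. That of the unfolded protein response list in ROS+++ versus ROS++, where camera's direction turned without ROS++ replicate 2, was -0.41 to -0.21.

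Fry pointed opposite to camera in 11 list results, because fry tests a list by itself and camera tests it against all other genes. Their medians were 0.13 (myelinating) and -0.0202 (unfolded protein response) in ROS+++ versus ROS+. In ROS+++ versus ROS++ they were -0.0629 (astrocyte), 0.0190 (kinase inhibitors), -0.11 (antioxidant), 0.14 (glycolysis), -0.14 (fatty acid oxidation), -0.20 (Notch), -0.24 (p53), -0.32 (unfolded protein response) and -0.0604 (respiratory chain). Of the 13 lists camera called in ROS+++ versus ROS++, fry lost those named above. Camera called none of these 11 opposite results, and fry called the unfolded protein response and Notch lists lower in ROS+++ than in ROS++ (adjusted p = 0.00241 and 0.0424, ranges over all alternatives 0.0024 to 0.99 and 0.042 to 0.48).

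Depth limits the values near 0. A gene with no read can lie at up to 0.119 to 0.236 CPM depending on the library, and in simulated data 29.3 to 38% of 2-fold changes were recovered. On the deposited scale, with its prior of 1 read, 9 values of named genes lost their call.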

Other observations

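The genes named in this part were chosen after their values were seen, except those the rule for named genes gave. The test of the NADPH oxidase hypothesis at the end was set before its result was seen.

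Single macrophage genes had the following levels in the higher gates, and no test of a difference between groups of them was made. Of genes known from perivascular and meningeal macrophages Mrc1 averaged 182 ± 76.7 CPM in ROS++ and 104 ± 101 CPM in ROS+++, Pf4 110.3 ± 67.1 and 70.05 ± 57.5, Cd163 43.9 ± 17.2 and 25.9 ± 29.6, and Cd209f 57.7 ± 39.01 and 11.9 ± 13.9. Of these 4 differences that of Cd209f passed the limma test (adjusted p = 0.00373) and the others did not, although that of Cd163 did in 3 alternatives (adjusted p range over all alternatives 0.0067 to 0.42). In ROS+ the means of Pf4, Cd163 and Cd209f were 0.0701, 0.0845 and 0.01898 CPM, under the floor of 3 reads, and that of Mrc1 was 0.213 CPM. The antigen presentation gene Cd74 averaged 426 ± 519.7 and 934 ± 1338 CPM with libraries far apart (not passed), and Ptprc rose from 24.6 ± 14.9 to 71.5 ± 16.8 CPM (adjusted p = 0.00394, range over all alternatives 0.00066 to 0.11). The microglial genes P2ry12 and Cx3cr1 averaged 27.4 ± 9.92 and 18.03 ± 14.01 CPM in ROS++ and 26.9 ± 11.7 and 29.7 ± 13.3 CPM in ROS+++.

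Mog and Mobp, genes of myelinating cells, were highest in ROS++ with wide spread. Mog averaged 19.4 ± 12.05, 146 ± 136 and 19.9 ± 6.82 CPM over the classes in order, and Mobp 8.39 ± 6.53, 167 ± 141 and 15.04 ± 3.24. Opalin stood at 198, 10.7, 86.04, 116 and 6.11 CPM in ROS++ replicates 1 to 5, and Hopx at 21.1, 8.91, 87.1, 135 and 8.19 CPM in the same libraries. The mean of the myelinating list was 7.74, 5.60, 7.31, 7.31 and 5.24 there. Pdgfra, the receptor of oligodendrocyte precursors, averaged 1171 ± 200.2 CPM in ROS+, 1157 ± 406 in ROS++ and 79.5 ± 92.4 in ROS+++.

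ROS+++ libraries also differed among themselves. The mean of the oligodendrocyte precursor list was 4.90, 2.35, 2.01 and 4.27 in replicates 1 to 4, while that of the microglia and macrophage list was 4.25, 6.44, 6.31 and 4.78. The heat shock gene Hspb8 was above both other classes in ROS++, at 5.74 ± 2.81, 56.05 ± 11.5 and 16.96 ± 11.8 CPM, unlike Hspa1a and Dnajb1. Of the 22 endothelial genes Cldn5 averaged 2.47 ± 2.11, 2.25 ± 3.01 and 3.22 ± 2.25 CPM and passed in none of the comparisons.

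A hypothesis tested here was that the macrophages of the higher gates carry the NADPH oxidase transcripts. For each gene the excess over ROS+ in ROS++ was divided by the excess in ROS+++. If macrophages alone carried the oxidase, its subunit genes should show the share of the macrophage genes. The median of the 6 subunits was 46.8% (quartiles 43.9 to 61.8%), below the macrophage quartiles of 65.1 to 119% (median 102%). Rac2 (66.4%) lay within the macrophage quartiles and Ncf1 (123%) above them. The macrophage list members Ptprc (34.02%), Selplg (49.4%), Itgam (57.3%), Cx3cr1 (59.3%), Ctss (63.1%) and Lyz2 (64.97%) lay below them. On class means the subunits as a set thus had a lower median share than the macrophage list as a set. These shares leave out the spread between libraries, and the macrophage list mean ran from 4.25 to 6.44 on the log2(CPM + 1) scale among ROS+++ libraries. The test therefore cannot decide whether macrophages carry the subunit transcripts. A macrophage subtype with its own ratio, such as that of Ptprc, may still carry them, and so may granulocytes or the precursor cells themselves, since sorted bulk libraries do not separate cell types.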
